A study of Mus musculus with 2 samples.

How the data were processed

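Chromatin accessibility was measured by ATAC-seq in liver pooled from mouse embryos of day 15.5 (strain B6NCrl, both sexes mixed). Per the labels, replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62, with 1 library each, and both formed 1 group. The purpose of the series was not stated beyond the tissue and age, and there was no second condition.

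The deposited files were peak lists and ranked peak lists in mm10, per the labels. The aligner, the peak caller and their versions were not given in the sources used here. Each peak carried a signal value that the authors computed against a background not described in the files, and it was used only to rank, describe or filter peaks within a list. Each peak also carried a −log10 p from the authors, unadjusted, and the ranked lists gave the authors' −log10 of the irreproducible discovery rate (IDR), a measure of how well a peak's rank repeats between peak sets. The authors called peaks for each replicate and for both together. In all, 8 lists were used. For each replicate they were its IDR thresholded and its pseudoreplicated (relaxed) peaks. For both libraries together they were the conservative IDR thresholded, the IDR thresholded, the replicated and the pooled pseudoreplicated (relaxed) peaks. A further 4 ranked lists were read to check the threshold and to set the replicates side by side. All 51628 peaks of the conservative list were found in the ranked list at an IDR of 0.05 or better. Read counts were not used here, so depth per library was unknown and no count model was fitted. Intervals on shares are exact binomial at 95% and cover counting error over regions only. The p-values of lists and motifs measure spread over genes or regions, not over animals.

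Overlapping peaks were merged to regions, each with the signal and summit of its strongest peak, on chromosomes 1 to 19, X and Y. Gene starts, exons and introns came from the GENCODE M21 annotation of the same build, and sequence from GRCm38. A promoter region lay within 500 bp of a TSS and a distal region did not. A distal region was assigned to the protein-coding gene with the nearest TSS within 50 kb of its summit, which placed 9743 of 12728 (76.5%). Nearest genes need not be the genes a region controls. The largest value over a gene's promoter regions was taken as its promoter signal.

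Gene lists, motifs, naming rules and the tests of the main results were fixed before the data were examined. Comparisons of pairs of lists, contrasts of motifs between distal and promoter regions, searches for sequence copies, and tests of explanations and of gene families were added later. The 21 lists held 461 entries that matched the annotation of 464 written, and Alas2, Hmbs, Mpl, Erg and Des each stood on a pair of lists. Ahsp, H19 and Anxa13 were not matched among protein-coding genes, and Es1 was read as Ces1c. Genes named in the text were, per list, the 3 with the highest promoter signal, the 2 with most distal regions and the first 2 in alphabetical order without a promoter region. Not all of them are printed. They were joined by the 10 genes with most distal regions, the 10 strongest distal regions, the 5 strongest replicate-specific regions of each replicate, and every region of 3 loci fixed in advance. The locus bounds reached 50 kb beyond the outermost genes.

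Replicates were compared by overlap of at least 1 bp, beside 100 random placements of the regions within their chromosomes, and by Spearman's rho of the −log10 p of matched peaks. Shares of accessible promoters were tested by Fisher's exact test against all other protein-coding genes. Distal regions per gene were tested by permutation, against 10000 random lists matched in 10 strata of the length of sequence nearest to each gene. Motif consensus words were searched on both strands in windows of 201 bp around the summits. They were tested by Fisher's exact test against copies shuffled with dinucleotide counts kept, and between distal regions assigned to the erythroid list and those assigned to the hepatoblast and mature hepatocyte lists. All tests were two-sided, and Benjamini-Hochberg adjustment ran over the 21 lists, the 60 motif tests or the 30 motifs, with a threshold of 0.05. Pairs of lists were compared by Fisher's exact test and by 100000 permutations of gene labels. Copies of a sequence were searched with blastn over at least 100 bp at 90% identity, and matches to the mitochondrial genome over at least 50 bp. Any match outside the region's own place counted as a copy, and assembly sequence outside the named chromosomes was searched too.

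The tests were tried on simulated data. In a single simulation of 21911 genes, 84 of 100 lists with 85% of open promoters against 50% were recovered, and 4 of 100 unplanted lists were called. All these lists were of equal size and larger than the urea cycle (8) and heme synthesis (10) lists, and as many were planted as not. The rates need not hold for lists of other sizes or where fewer lists differ. Of 100 lists with 4 times the distal regions, 98 were recovered, and 3 of 100 unplanted lists were called. Of 15 motifs planted in 5% of 4000 windows, all 15 were recovered. Of 15 unplanted motifs 1 was called, namely GATA with E-box, whose word holds most of the planted GATA word.

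Alternatives were windows of 200 and 1000 bp around a TSS, distances of 20 and 100 kb, other peak lists, the stronger part of the list by signal, peaks not merged, a reciprocal overlap of 50%, each replicate alone, motif windows of 50 bp each side, flanking sequence 1000 bp away, and random lists matched on CpG content or on an open promoter. Peaks outside the named chromosomes were left out. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, along with samtools 1.23.1 and blastn 2.17.0. The random seed was 20.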

Results

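ATAC-seq finds stretches of chromatin that are open to a transposase, and it was run here on the liver of mouse embryos at day 15.5. At this age the liver makes most of the embryo's blood, mainly red cells, while its own hepatoblasts mature into hepatocytes and bile duct cells. The data comprised 2 libraries of 1 group. Replicate 1 came from a pool of 78 embryos and replicate 2 from a pool of 62, each with both sexes mixed. No other tissue, age or treatment was included, so the comparisons were between the replicates, between classes of genomic position, and between genes known from different cell types. The deposited peak lists gave positions and a signal value per peak but no read counts, so the depth of the libraries was unknown. All positions are in mm10, counted from 1.

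The open chromatin of both pools of livers largely coincided, which addressed how far separate pools of embryos gave the same map. Replicate 1 had 20431 accessible regions over 14.8 Mb, and 81.3% of them (16614; exact 95% interval 80.8% to 81.9%) overlapped a region of replicate 2 by at least 1 bp. Replicate 2 had 17974 regions over 13.3 Mb, and 93.0% of them (16722; 92.7% to 93.4%) overlapped a region of replicate 1. Random placement of the regions on their chromosomes gave 1.07% and 1.19%. The lists shared 12 Mb of the 16.1 Mb that either covered. Across 85969 matched peaks, the −log10 p of the replicates had a Spearman's rho of 0.822, over peaks that are not independent replicates.

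Regions found in a replicate and missing even from the other's relaxed list were few and weak. Replicate 1 had 293 of them, 1.43% of its regions, with a median signal of 5.38 against 11.3 for all its regions. Replicate 2 had 78, or 0.434%, with a median signal of 3.07 against 11.2. The strongest of replicate 1 lay at chromosome 3: 73125197-73125495 (signal 14), with no gene start within 50 kb. It was followed by a region at chromosome 6: 108638244-108638809 (signal 11.7) near Bhlhe40, which encodes a transcription factor of the circadian clock. Another lay near Pdcd10, a gene of vascular integrity, with a signal of 10.9. The strongest of replicate 2 lay at chromosome 1: 151779347-151779604 near Edem3 (signal 8.19), which acts in the disposal of misfolded glycoproteins, and others lay near Rnf19b (7.59), a ubiquitin ligase, and Dab1 (7.42), a reelin pathway gene. These regions were too few to compare the pools by cell type, since no gene list held more than 2 of the 293 or 1 of the 78 (Fisher's exact tests, smallest unadjusted p 0.210). When a region only had to be missing from the other replicate's stricter list, the counts rose to 3817 and 1252. No list differed past the threshold between these larger sets (Fisher's exact tests, smallest unadjusted p 0.213). Mature hepatocyte, coagulation and urea cycle lists each held 8 of the 3817 and 0 of the 1252. Hepatoblast and erythroid lists each held 15 and 3. The heme synthesis, endothelial, cell cycle, neuronal and lung, gut, pancreas and kidney lists leaned the other way.

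Gene starts held a large part of the open chromatin of the fetal liver. The conservative list of peaks that passed the authors' reproducibility threshold merged to 24008 regions over 17.8 Mb. Of these, 47.0% (11280; exact 95% interval 46.4% to 47.6%) lay within 500 bp of an annotated transcription start site (TSS), 11.8 times the 3.99% of random placements. Introns held 31.8% of the regions against 42.6% at random, and sequence between genes held 18.5% against 50.2%. Exons held 2.76% against 3.21%. Promoter regions were wider than distal regions, with a median width of 963 bp against 510 bp, and had a higher median signal, 12.9 against 8.21. The share near a TSS depended on the list, at 29.4% in the pooled relaxed list of 50792 regions.

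Promoters of red cell genes were open in the fetal liver, those of hepatocyte genes were open in part, and those of most other cell types were closed by the authors' conservative threshold. The genome as a whole set the background, with a region at the TSS of 10714 of 21911 protein-coding genes (48.9%). The erythroid list had 31 of 34 promoters with a region, 1.87 times the share of other genes (Fisher's exact test, two-sided, adjusted p 2.79e-06). All 10 genes of heme synthesis had one (adjusted p 0.00117), as did all 20 cell cycle genes and all 20 housekeeping genes (adjusted p 3.18e-06 for each). The heme synthesis call did not hold in the stronger part of the list by signal. The fetal hepatoblast list, with its plasma proteins and liver transcription factors, had 17 of 34 (ratio 1.02, adjusted p 1). Coagulation and complement genes had 13 of 28 (adjusted p 0.894), urea cycle genes had 5 of 8 (exact test, adjusted p 0.582), and genes of blood stem and progenitor cells had 10 of 24 (adjusted p 0.601). Genes of mature hepatocyte metabolism had 4 of 29, 0.282 times the share of other genes (adjusted p 0.000292).

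Among the other cells of the liver, the lists stayed below the background in the conservative list, and some rose in the pooled relaxed list. Macrophage and neutrophil genes had a promoter region in 1 of 30 cases (adjusted p 1.42e-06), megakaryocyte and mast cell genes in 3 of 22 (0.00125), and B and T lymphocyte genes in 1 of 18 each (0.000292 for each). Sinusoidal endothelium had 3 of 25 (0.000295), stellate cells and mesenchyme had 3 of 23 (0.000837), and bile duct genes had 0 of 14 (0.000292). The lists of cells foreign to the liver gave the level of closed promoters in the conservative list. Neuronal genes had 2 of 25, muscle genes 1 of 24, the joint list of lung, gut, pancreas and kidney 1 of 25, epidermal genes 1 of 15 and germ cell genes 1 of 15, with adjusted p between 7.24e-06 and 0.00125. Hepatoblast genes had more open promoters than mature hepatocyte genes (adjusted p 0.00466) and fewer than erythroid genes (adjusted p 0.00112, Fisher's exact tests of 6 pairs of lists chosen after the values were seen). CpG content limits the first contrast, since random genes of equal CpG content gave 36.2% for the hepatoblast and 12.3% for the mature list, and neither list passed against them (adjusted p 0.0552 and 1).

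**Figure D1:**
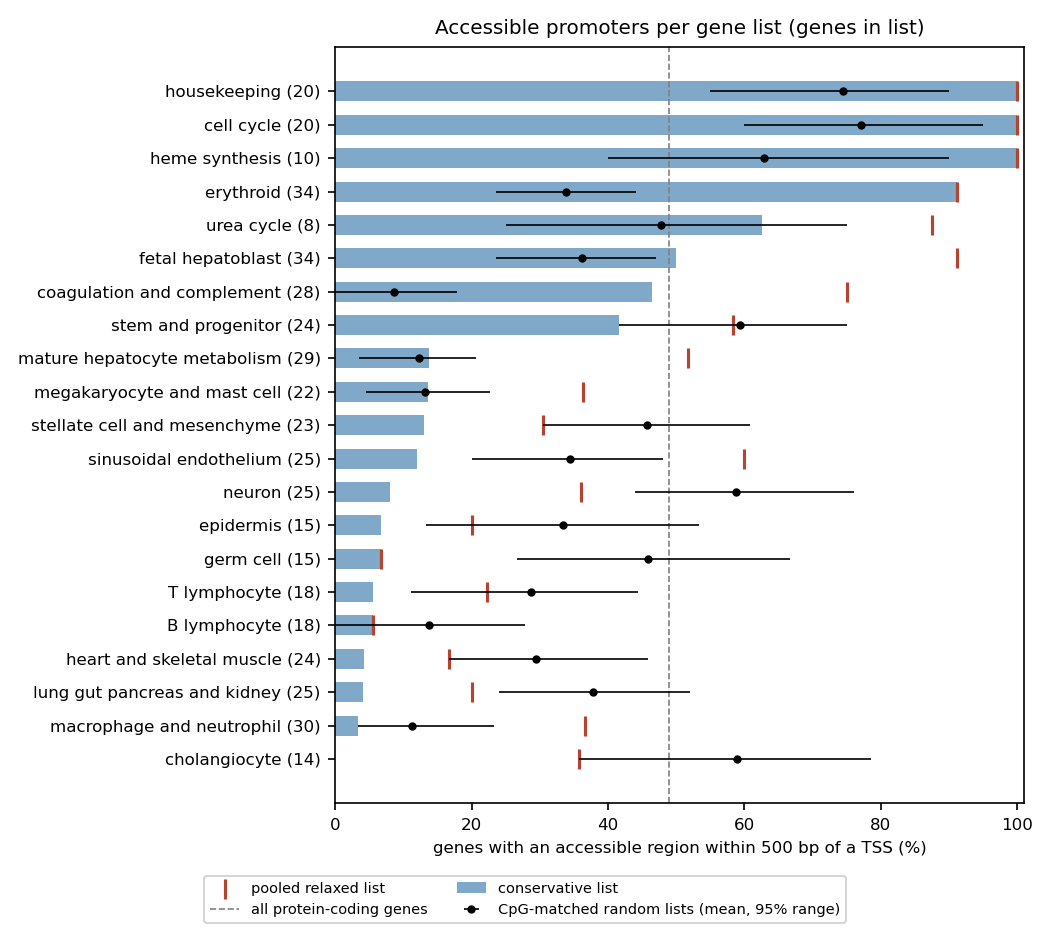
Share of genes of each list with an accessible region within 500 bp of a TSS (percent), in the conservative list (bars) and the pooled relaxed list (red marks); black points and lines are means and 95% ranges of random lists matched on CpG content, and the dashed line is all protein-coding genes. Erythroid genes reached 91.2% in both lists, while fetal hepatoblast genes rose from 50% to 91.2%.

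The peak threshold and the base composition of promoters both changed which lists stood out. In the pooled relaxed list, 31 of 34 fetal hepatoblast promoters had a region, the same number as in the erythroid list (ratio 1.59, adjusted p 0.000129 for each), and mature hepatocyte genes had 15 of 29. Sinusoidal endothelium reached 15 of 25 in that list (ratio 1.04, adjusted p 0.885). Bile duct genes (5 of 14, adjusted p 0.137), megakaryocyte and mast cell genes (8 of 22, 0.0736) and neuronal genes (9 of 25, 0.0616) no longer passed as below. The remaining lists below the background stayed below. In replicate 2 alone the fetal hepatoblast list fell to 9 of 34, below the background (ratio 0.593, adjusted p 0.0417), against 12 of 34 in replicate 1 alone. Coagulation and complement genes fell below it too in replicate 2 alone, with 5 of 28 (ratio 0.400, adjusted p 0.00458). Against random genes of equal CpG content, erythroid promoters were open 2.70 times as often (91.2% against 33.8%, permutation adjusted p 0.0007). Coagulation and complement promoters were then open 5.44 times as often (46.4% against 8.53%, adjusted p 0.0007), and mature hepatocyte promoters no longer stood below (13.8% against 12.3%, adjusted p 1). Megakaryocyte and mast cell genes reached the matched level (ratio 1.03, adjusted p 1). Macrophage and neutrophil and B lymphocyte genes stayed lower (ratios 0.298 and 0.406) but no longer passed (adjusted p 0.263 and 0.548).

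Individual promoters followed these lists, with signal values that are the authors' own and rank peaks within the conservative list. Among erythroid genes, the highest values were at Trim10 (22.1), which codes for a protein of red cell differentiation, Epb42 (22), a protein of the red cell membrane, and Slc25a37 (16.5), the iron importer of mitochondria. Cpox (17.5), Ppox (15.2) and Uros (14.1), enzymes of heme synthesis, were also among the strong promoters. No region lay at Hba-x or Hbb-bh1, globin genes of the earlier embryonic red cells. Among hepatoblast genes, Foxa3, a liver transcription factor, had 13.3, Gpc3, an oncofetal proteoglycan, had 10.3, and Fga, the fibrinogen alpha chain, had 10.5 with a region in replicate 1 but not in replicate 2. Alb and Afp, which encode the main plasma proteins of the fetus, had none in the conservative list. In relaxed lists a peak lay at the Alb start in replicate 1 (signal 4.43) and at the Afp start in replicate 1 (2.75), and none lay there in replicate 2.

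Genes of metabolism with open promoters included Oat (16), an ornithine enzyme, Glul (15.7), glutamine synthetase, Asl (11.9), the argininosuccinate lyase of the urea cycle, Slc25a13 (11.5) and Slc25a15 (10.9), carriers that feed that cycle. Sult2a8, a bile acid sulfotransferase, had 10.1 and a region in replicate 1 only. Aldob of fructose metabolism, Car3, a carbonic anhydrase, and the urea cycle enzymes Arg1 and Cps1 had none. Clotting factor gene F10 had 12.6, Pros1, which encodes protein S, had 12.1 with a region in replicate 1 but not in replicate 2, and Plg, the plasminogen gene, had 10.4, while C4bp and C5ar1 of the complement system had none. Runx1 (14.4), Cbfa2t3 (13.3) and Lyl1 (12.5), regulators of blood stem cells, had strong promoters, and Cd34 and Erg of the same list had none.

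Some genes of scarcer or foreign cells had an open promoter against the trend of their list. Irf8, a factor of macrophage development, had 9.84, and Gp1ba, a platelet receptor gene, had 12. Ebf1 of B cells had 8.48 and Lck of T cells had 10.8. Endothelial receptors Tek (7.0) and Tie1 (5.11) and the endothelial factor Egfl7 (5.76) had weaker regions, as did Pdgfra (6.61), Lhx2 (5.65) and Reln (4.90) of stellate cells. Foreign genes with a region were the neuronal Map2 (10.1) and Syp (8.61), the muscle myosin chain Mylpf (12.5), the gut stem cell gene Lgr5 (5.31), the epidermal gene Perp (13.6) and the germ cell gene Dazl (19.3). Ebf1, Lck, Tek, Tie1, Pdgfra, Lhx2 and Lgr5 had no region in the list of either replicate alone, and Egfl7, Map2 and Syp had one in a lone replicate. For comparison, the cell cycle genes Ccnb2, Ccnb1 and Mcm3 had 22.6, 19.6 and 19.3, and the housekeeping genes Pgk1, Atp5b and Rplp0 had 18.4, 18.1 and 17.4.

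Distal regions, which include enhancers, had their highest mean count around genes of the red cell lineage among the cell types listed. Direct tests set the erythroid list only against the hepatoblast and neuronal lists. Erythroid genes had a mean of 2.68 distal regions (SD 1.85 over 34 genes) against 0.373 for random genes with as much surrounding sequence, a ratio of 7.17 (permutation test, two-sided, p 0.0002, the smallest that 10000 random lists can give, adjusted p 0.0021). Of the erythroid genes, 31 of 34 had at least 1. Heme synthesis genes had 2.40 (SD 1.35) against 0.311 (ratio 7.71, adjusted p 0.0021), with 9 of 10 genes having at least 1. Stem and progenitor genes had 1.58 (SD 2.30) against 0.564 (ratio 2.81, adjusted p 0.0182), and housekeeping genes had 1.00 (SD 1.62) against 0.319 (ratio 3.13, adjusted p 0.0399). Fetal hepatoblast genes had 1.03 (SD 1.17) against 0.482 and missed the threshold (ratio 2.14, adjusted p 0.0638), as did megakaryocyte and mast cell genes with 0.909 (SD 1.51) against 0.368 (ratio 2.47, adjusted p 0.084). The other 15 lists lay between ratios of 0.230 for T lymphocytes and 1.93 for the urea cycle, with adjusted p of 0.208 or more. Mature hepatocyte genes had 0.552 (SD 1.02) against 0.469.

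Erythroid genes also had more distal regions than hepatoblast genes when these lists were set against each other (permutation adjusted p 0.00015, a pair chosen after the values were seen). The stem and progenitor and the housekeeping lists no longer passed in replicate 2 alone (ratios 2.70 and 2.93, adjusted p 0.0868 and 0.171). In the pooled relaxed list the fetal hepatoblast list did (ratio 2.40, adjusted p 0.0014), and housekeeping genes lost the call when random genes were also matched on an open promoter (ratio 2.11, adjusted p 0.157). Megakaryocyte and mast cell genes passed with that matching, with peaks not merged and in the stronger part of the list by signal.

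**Figure D2:**
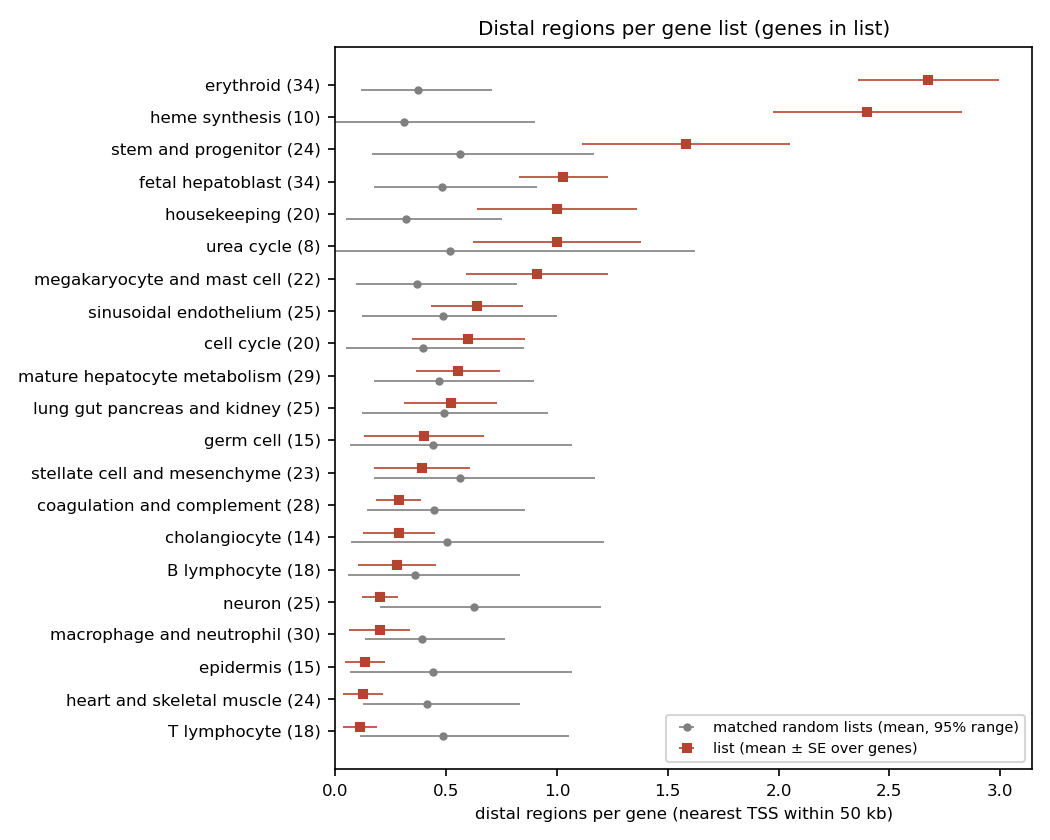
Mean number of distal regions per gene in each list (red squares, with the standard error over genes) and in random lists matched on surrounding sequence (grey, mean and 95% range). Erythroid (2.68) and heme synthesis (2.40) genes lie furthest from their random lists.

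The genes with the most distal regions in their lists were of several kinds. Zfpm1, the GATA1 cofactor also known as FOG1, had 8, and Ank1, the ankyrin of the red cell membrane, had 7. Cbfa2t3 and Ikzf1, regulators of stem cells and lymphocytes, had 8 and 6, and Cpox and Tmem14c of heme synthesis had 4 each. Among liver genes, Alb had 4, Afp had 3, and Hpd, a tyrosine breakdown enzyme, had 4. F2rl2, a thrombin receptor, had 5, Fcgr3, an immunoglobulin receptor of myeloid cells, had 4, and Blnk, a B cell adaptor, had 3. Eng of endothelium, in a tie, had 3. Reln and Tagln of the stellate cell and mesenchyme list had 4 and 3, and Sox4, from the bile duct list, had 2. Ubc and Eef1a1, housekeeping genes, had 6 and 4, and Aurkb of the cell cycle had 4. Scgb1a1 of the lung and Tnp1 of sperm had 4 each although their promoters were closed. Over all protein-coding genes, the largest numbers were at Usp7 (13), a deubiquitinase, and Sox6 (12), a repressor of embryonic globin genes. Fam53b, Mbp, Sgms1, Tbxas1 and Zfp217 had 11 each, and Ago2, Cd47 and Chst11 had 10 each. Several of these counts were more than 1.5 times lower in the shorter list of a replicate alone. In replicate 2 they were 7 at Usp7, 6 each at Tbxas1, Zfp217 and Ago2, 5 at Zfpm1 and 4 at Ank1. They were 3 at F2rl2 and Ubc, and 2 at Alb, Hpd, Tmem14c, Reln, Eef1a1 and Aurkb. They were 1 at Eng, Tagln, Sox4 and Scgb1a1 and 0 at Afp. In replicate 1 they were 8 at Usp7, 6 at Zfp217 and Ago2, 4 at Ank1, 2 at Eef1a1 and Scgb1a1 and 0 at Eng.

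The globin clusters had many open regions in the control sequences that switch globin genes on. The beta-globin cluster with its flanks (chromosome 7: 103762524-103903216) had 13 regions, of which 10 were distal. The adult genes had open promoters, at 103813313-103814176 for Hbb-bt (signal 9.71) and 103827364-103828221 for Hbb-bs (signal 10.0). A row of 5 regions followed upstream of Hbb-y, at 103859140-103859501 (signal 12.1), 103860923-103861287 (9.17), 103865681-103866127 (12.5), 103870544-103871245 (11.9) and 103877078-103877495 (13.1), where the locus control region of the cluster lies, and each was called in both replicates. The embryonic gene Hbb-bh1 had no promoter region, and a region 1.7 kb upstream of it (103844645-103845367, signal 7.24) was called in replicate 1 but not in replicate 2. Hbb-y, another embryonic gene, had no promoter region either.

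The alpha-globin cluster (chromosome 11: 32175628-32347298) had 17 regions, of which 11 were distal. Its strongest distal regions lay in introns of Nprl3, the neighbouring gene whose introns hold alpha-globin enhancers. They were at 32255996-32256891 (signal 23.1), 32250727-32251397 (21.6) and 32245191-32246049 (17.7). The promoter region of Snrnp25, in the same locus, had a signal above all but the first of these. The Hba-a1 promoter at 32283341-32284897 had a signal of 5.80 and the Hba-a2 promoter at 32296069-32297320 had 8.12, values that reads shared between these near-identical genes make uncertain, as they do for Hbb-bt and Hbb-bs. The embryonic Hba-x had no region. Around Alb and Afp (chromosome 5: 90410897-90558907) there were 8 regions, all distal. The strongest lay 29.6 kb upstream of the Alb start at 90430989-90431502 (signal 12.9) and 13.1 kb upstream of it at 90447470-90448212 (11.5), both called in each replicate. A region 2.3 kb upstream of the Afp start, at 90488236-90488769 (7.11), was called in replicate 1 but not in replicate 2.

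**Figure D3:**
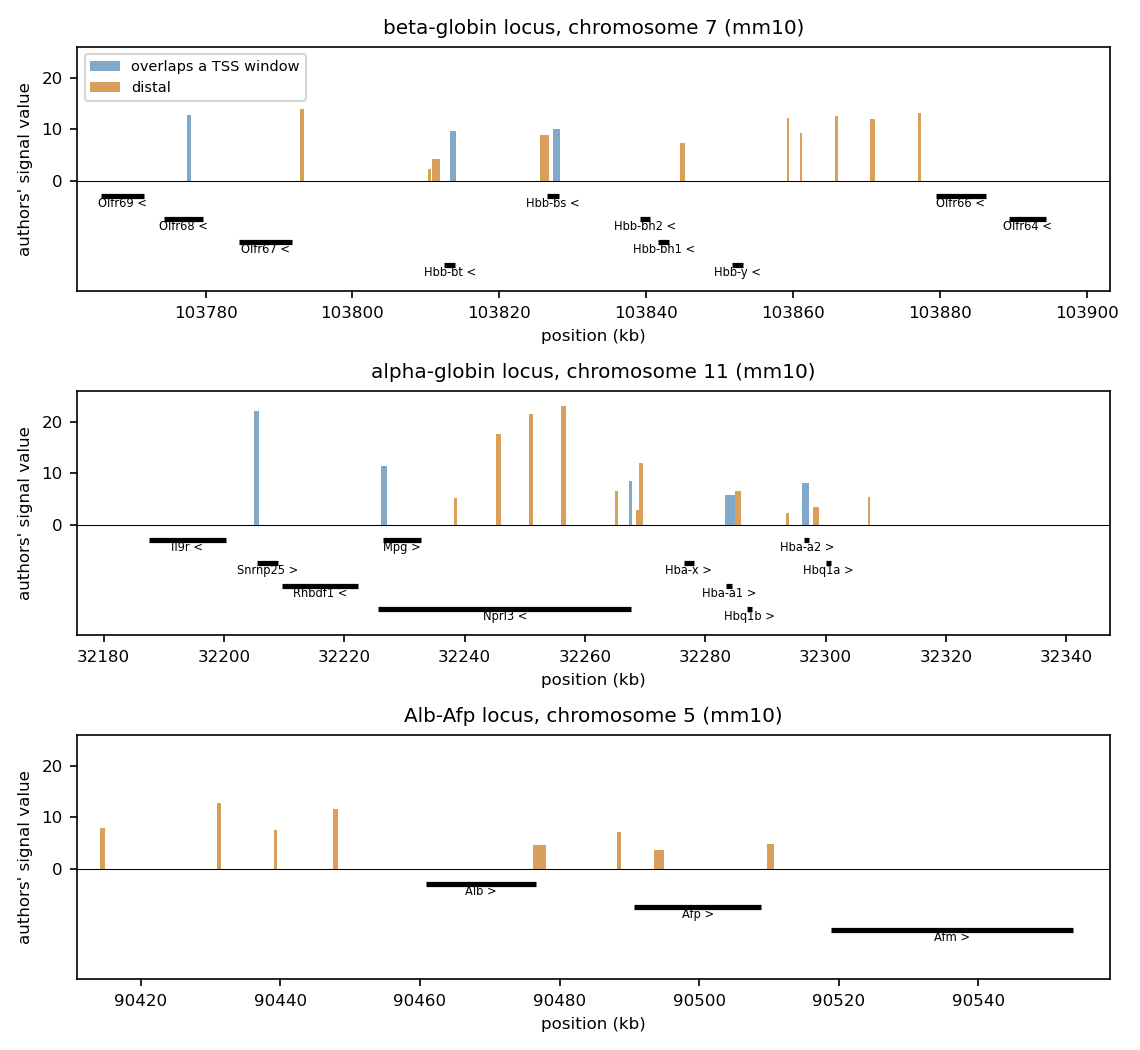
Accessible regions of the conservative list at the beta-globin, alpha-globin and Alb-Afp loci (mm10 position against the authors' signal value per region), with the genes drawn below each panel. The highest region, with a signal of 23.1, lies in an intron of Nprl3 beside the alpha-globin genes.

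Sequence under the summits of distal regions was rich in GATA sites. The motif does not tell GATA1 of red cells from other GATA factors. Gata1 (signal 10.1), Gata4 (8.01) and Gata6 (6.52) all had a promoter region. A GATA site lay within 100 bp of 28.5% of 12728 distal summits against 3.87% of shuffled copies of the same sequence (odds ratio 9.91, Fisher's exact test, adjusted p below the smallest number the software can write). The composite bound by TAL1 and GATA1, searched as the CTG of an E-box before a GATA core, lay at 16.4% against 0.959% (odds ratio 20.3). Its word holds most of the GATA word, so these results are not separate. The KLF word took CACCC, which KLF1 of red cells shares with other KLF factors, and also CGCCC, a core of the SP1 word. KLF sites may therefore include sites of SP factors. KLF sites lay at 13.1% against 2.68% (odds ratio 5.5, adjusted p 7.26e-226), and the NFE2 site at 2.05% against 0.165% (odds ratio 12.7, adjusted p 1.16e-53). Among 6 liver motifs, FOXA lay at 5.51% against 1.81% (odds ratio 3.15, adjusted p 6.74e-57), HNF4A at 2.51% against 0.927% (odds ratio 2.75, adjusted p 2.84e-22), and HNF1 at 7 windows against 0 (adjusted p 0.0218, and 1 in replicate 2 alone). CEBP missed the threshold at 2.05% against 1.72% (odds ratio 1.20, adjusted p 0.0783), as did NR5A2 at 1.28% against 1.11% (odds ratio 1.16, adjusted p 0.271) and ONECUT at 1.19% against 1.18% (odds ratio 1.01, adjusted p 1). The liver motifs depended on the background. Against flanks 1000 bp away in place of shuffled copies, distal CEBP passed as above (odds ratio 1.81, Fisher's exact test, adjusted p 1.99e-11). FOXA stayed above with a lower odds ratio of 1.3 (adjusted p 3.94e-07), as did HNF4A with 2.18, while ONECUT turned to below (0.778). Sites of CTCF, an insulator protein, lay at 1.67% against 0.157% of shuffled copies (odds ratio 10.8, adjusted p 2.57e-41). Of 30 motifs tested, 19 were above the shuffled copies in distal regions and 5 below, with 2 below in replicate 2 alone and 3 in replicate 1 alone.

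Promoter summits were rich in sites of NFY, SP1 and KLF factors, where the KLF word may also take sites of SP factors. NFY sites lay at 22.3% of 11280 promoter summits against 5.66% of shuffled copies (odds ratio 4.78, adjusted p 4.17e-299), SP1 sites at 20.8% against 2.97% (odds ratio 8.59), and KLF sites at 20.3% against 5.11% (odds ratio 4.74). ETS sites lay at 7.53% (odds ratio 10.7), NRF1 sites at 5.86% (odds ratio 12.9) and YY1 sites at 4.74% (odds ratio 24.4). GATA sites lay at 3.17% of promoter summits against 28.5% of distal summits (odds ratio of distal to promoter 12.2), while KLF sites were less frequent at distal than at promoter summits (odds ratio 0.593, adjusted p 5.78e-50, contrasts chosen after the values were seen). Of the 30 motifs, 18 were above the shuffled copies at promoters and 2 below. Against flanks 1000 bp away in place of shuffled copies, 14 were below, and GATA at promoters turned from above (odds ratio 2.67) to below (0.772), as did FOXA (0.328) and HNF4A (0.644), while the enrichment of GATA in distal regions kept its direction.

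**Figure D4:**
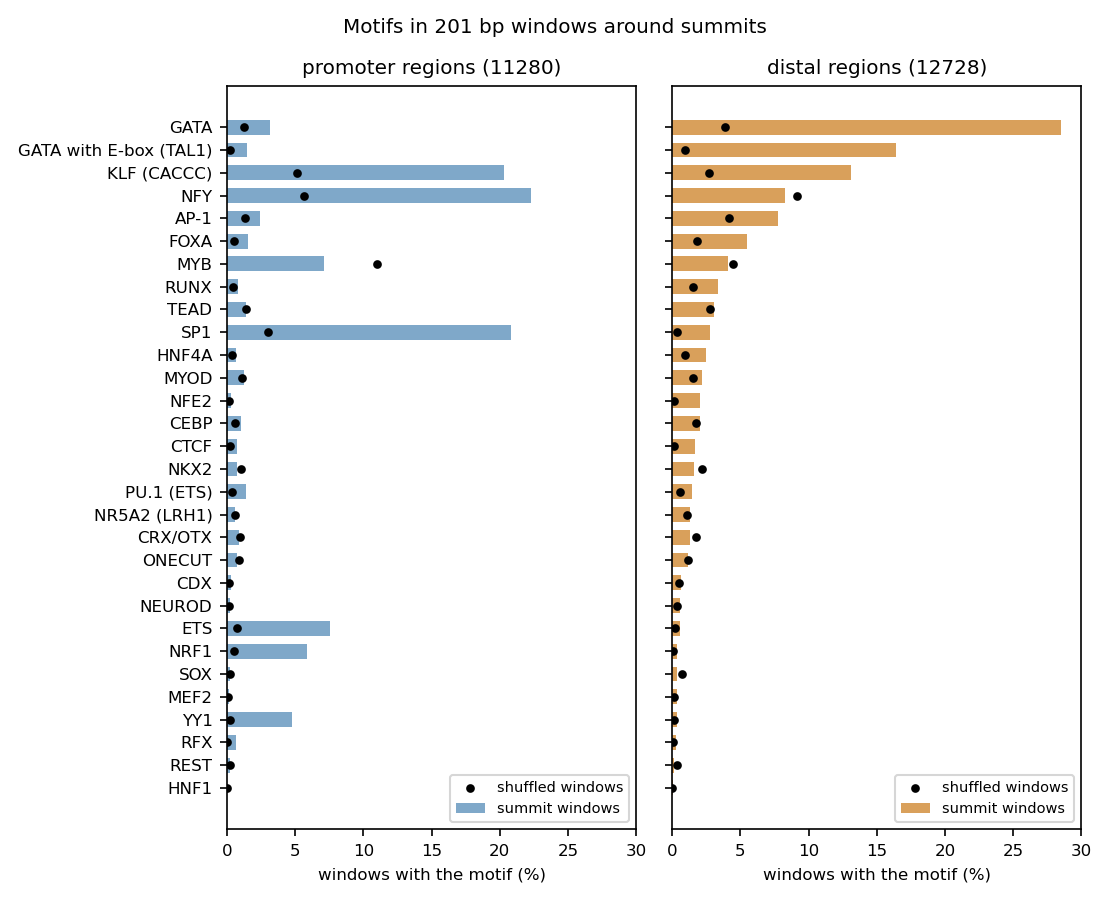
Percentage of 201 bp windows around summits with each motif, in promoter (left) and distal regions (right); bars are summit windows and black points are shuffled copies of them. GATA sites lie at 28.5% of distal and 3.17% of promoter summits.

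Distal regions near erythroid genes and those near hepatocyte genes did not differ in motif content past the threshold in the conservative list. GATA sites lay at 31.9% of 91 regions assigned to erythroid genes and at 11.8% of 51 assigned to genes of the hepatoblast and mature hepatocyte lists (odds ratio 3.51, Fisher's exact test, p 0.00825, adjusted p 0.0955). The TAL1 composite and KLF sites each lay at 23.1% against 5.88% (p 0.00955, adjusted p 0.0955). FOXA sites of the liver lay at 3.30% near erythroid genes and 5.88% near hepatocyte genes (adjusted p 1), and HNF4A sites at 1.10% and 3.92% (adjusted p 1). No motif of the 30 passed, against 3 in the larger replicated list, where GATA sites lay at 23.8% of 147 and 8.18% of 159 regions (adjusted p 0.00712). The others were KLF (adjusted p 0.0212) and the TAL1 composite (0.0299), which is not separate from GATA.

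The strongest distal regions by signal lay near no erythroid or hepatocyte gene of the lists and were mostly sequences with further copies in the genome. The highest values were at chromosome X: 143482935-143483180 near Pak3 (58), a neuronal kinase gene, and at chromosome 2: 69355469-69355735 near Abcb11 (55.4), which encodes the bile salt pump of hepatocytes. Next came chromosome 16: 18533121-18533398 near Rtl10 (47.5), a gene derived from a retrotransposon. The following 4 had no protein-coding start within 50 kb, at chromosome 5: 60042743-60043140 (46.5), chromosome 1: 102628109-102628399 (45.5), chromosome 10: 96077546-96077953 (41.8) and chromosome 2: 3964421-3964690 (40.9). The last were chromosome 16: 17222189-17222588 near Hic2 (39.3), a transcriptional repressor, chromosome 6: 49236380-49236683 near Igf2bp3 (38.3), a fetal RNA-binding protein, and chromosome 17: 70963583-70963968 near Myl12b (37.7), a myosin light chain. Another copy of the sequence (at least 100 bp at 90% identity) existed elsewhere in the genome for 9 of these 10 summits, for 2 of them only in the mitochondrial genome. The count was 8 of 100 for other distal regions. The regions near Abcb11, on chromosome 5 and on chromosome 10 aligned to the mitochondrial genome over 129, 358 and 352 bp. By −log10 p the 10 regions ranked between 5 (chromosome 17) and 1220 (chromosome 2: 3964421-3964690) among distal regions, so they were not all the strongest by that measure.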

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

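The tests of CpG content, of the authors' threshold and of sequence copies were chosen after related values had been seen, and the test of cell shares was not.

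The ranked list that sets the replicates side by side contained 174 peaks with an IDR of 0.05 or better that were absent from the conservative list. Those on the chromosomes analysed entered the rank correlation of the replicates, but counts from the conservative list leave these peaks out. Of these, 129 lay on the chromosomes analysed, in 51 regions with a median −log10 p of 298, and 45 lay elsewhere. The highest −log10 p of all, 13519, belonged to a region at chromosome 1: 24611587-24616163, all of whose 4577 bp align to the mitochondrial genome, and the highest in the conservative list was 11138. The values argue against mitochondrial DNA placed on nuclear copies for most of the 51 regions, because that region on chromosome 1 was their only match found (1.96% of 51). The 45 peaks elsewhere were not searched. Reads shared between repeated copies may account for a large part: 60.8% of the left-out regions (31 of 51, of which 1 only in the mitochondrial genome) had another copy in the genome, against 8 of 100 other distal regions (Fisher's exact test, p 7.11e-12). A filter against such sequence by the authors is a candidate explanation that these lists cannot test. No biological explanation was tested.

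Hepatocyte genes had fewer open promoters than erythroid genes in the conservative list, with 34 of 91 members of the hepatoblast, mature hepatocyte and coagulation lists against 31 of 34. These lists differed, with 17 of 34, 4 of 29 and 13 of 28, so the mature list lowered the joined share. Expression was not measured, so whether genes of mature metabolism were active at day 15.5 was unknown. CpG content as the cause is excluded for the hepatoblast list. Within strata of CpG content the erythroid share stayed above the hepatoblast share by 45.4 percentage points, against 41.2 without strata (stratified permutation p 0.00015). Against the joined lists the difference within strata was 49.9 points (p 0.0001, the smallest that its permutations can give).

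The authors' threshold may explain part of that pattern. Among members of the joined hepatocyte lists without a conservative promoter region, 57.9% (33 of 57) had one in the pooled relaxed list, against 16.6% of other genes without one (Fisher's exact test, p 2.58e-12), so many of these promoters were open with a weaker peak. Sinusoidal endothelium rose in the same way (12 of 22, adjusted p 0.000388). A smaller share of hepatocytes than of erythroid cells in the tissue could have weakened those peaks and stays open. It would lower the signal of all hepatocyte regions, but the median distal signal of hepatocyte genes was 1.05 times that of erythroid genes (bootstrap 95% interval 0.804 to 1.35), and the ratio for promoters was 0.765 (0.566 to 0.958). Before the test, a distal interval reaching 1 had been set as grounds to exclude this explanation. That bound was dropped after the value was seen, because an interval down to 0.804 still allows a lower signal and because the list omits regions under its threshold, which removes the weakest hepatocyte regions first. Distal regions of the pooled relaxed list gave 1.13 (0.864 to 1.37). The labels give no cell composition, so a biological difference between the lineages in promoter opening was not tested.

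The 10 strongest distal regions by signal had signals from 37.7 to 58 and were narrow (246 to 408 bp) against a median of 510 bp over all distal regions. By −log10 p they ranked between 5 and 1220 among distal regions. For 7 of the 10 regions the longest alignment found to the mitochondrial genome at 90% identity was 0 bp. This argues against mitochondrial reads there, though the search could miss short or diverged matches. The summit window of the region at chromosome 2: 3964421-3964690 matched 0 bp elsewhere in the assembled genome at 90% identity. Reads shared between copies stay open for that region, because the search covered only the summit window. The search could also miss short or diverged matches and copies absent from the assembly. For the other regions reads shared between copies may be the explanation, but a match at 90% identity does not show that reads were shared. Of the 10 regions, 9 had another copy in the genome, against 8 of 100 others (Fisher's exact test, p 4.86e-08). The copy was in the nuclear genome for 7 of the 9 (p 1.96e-05) and only in the mitochondrial genome for 2. Mitochondrial reads stay open for 3 of the 10, which aligned to the mitochondrial genome against 0 of 100 others, because peak lists do not tell reads of the mitochondrial genome from those of its nuclear copy. No biological explanation was tested.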

How the results depend on the processing

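Settings chosen after the data were examined were the pooled relaxed list, the stronger part by −log10 p and the overlap with the other replicate's relaxed list. No paired analysis was possible because there was 1 group. Read depth was unknown, so how far it limits weaker peaks was not measured. Causes of the changes below were not tested unless given.

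For promoters, 189 of 210 comparisons of a list under an alternative kept their call (above, below or neither), among them all for erythroid, cell cycle and housekeeping lists. With 200 bp or 1000 bp windows, with the series IDR list and in replicate 1 alone, every list did. Against a background matched on CpG content, the ratio became 5.44 for coagulation and complement, 1.12 for mature hepatocyte metabolism and 1.03 for megakaryocyte and mast cell, 0.298 for macrophage and neutrophil and 0.406 for B lymphocyte (adjusted p 0.0007, 1, 1, 0.263 and 0.548). In the replicated list, the fetal hepatoblast ratio was 1.54 and passed, while cholangiocyte (0.625), mature hepatocyte (0.784) and endothelium (0.909) no longer did. In the pooled relaxed list, fetal hepatoblast was 1.59 and passed, endothelium turned to 1.04, and cholangiocyte (0.621), mature hepatocyte (0.899), megakaryocyte and mast cell (0.632) and neuron (0.626) no longer passed, so 8 lists were below instead of 13. In the stronger part by signal, coagulation and complement was 0.544 and passed, and heme synthesis was 1.53 and did not. In the stronger part by −log10 p, coagulation and complement was 0.485 and fetal hepatoblast 0.533, both below. Leaving out a replicate gave ratios of 0.400 to 0.770 for coagulation and complement and 0.593 to 0.761 for fetal hepatoblast.

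For distal regions, 212 of 231 comparisons kept their call and none changed direction past the threshold, with erythroid and heme synthesis above in each. Fetal hepatoblast passed with the series IDR list (2.34), within 20 kb (2.53), in the relaxed (2.40) and replicated (2.44) lists and with peaks not merged (2.69). Housekeeping no longer passed when matched on open promoters (2.11), within 20 kb (3.02), with peaks not merged (2.61), or in the stronger part by −log10 p (3.21) or by signal (2.70). Megakaryocyte and mast cell passed when matched on open promoters (3.37), with peaks not merged (2.83) and in the stronger part by signal (3.21). Neuron passed below in the relaxed (0.292) and replicated (0.328) lists, so 1 list lay below in each instead of 0. Stem and progenitor did not pass within 20 kb (2.36) or in the stronger part by signal (2.46). Leaving out a replicate left 2 to 4 lists above, with ratios of 2.93 to 3.58 for housekeeping and 2.70 to 3.14 for stem and progenitor.

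The share near a TSS was 44.4% with 200 bp windows, 49.96% with 1000 bp, 29.4% in the relaxed and 30.1% in the replicated list, 60.1% with peaks not merged, and 57.1% and 52.7% in the stronger part by −log10 p and by signal. It was 51.4% to 55.7% with a replicate left out. Replicate overlap was 78.1% and 88.7% at a reciprocal overlap of 50%, 76.1% and 84.5% between relaxed lists, 84.0% and 94.7% in the stronger part, 87.0% and 95.5% with peaks not merged, and 98.6% and 99.6% against the other's relaxed list. The rho of 0.822 became 0.843 at an IDR of 0.05 or better, and Pearson's r on a log2 scale with a pseudocount of 1 was 0.885. Replicate-specific regions numbered 3817 and 1252 when absence from the other's IDR list was enough, by construction.

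For motifs, 290 of 360 comparisons kept their call, with GATA, the TAL1 composite, KLF and FOXA above in distal regions in each. Against flanks 1000 bp away, 14 promoter motifs were below instead of 2. Promoter odds ratios turned to 0.760 for AP-1, 0.161 for CDX, 0.778 for CEBP, 0.328 for FOXA, 0.772 for GATA, 0.644 for HNF4A, 0.399 for MEF2, 0.403 for RUNX and 0.449 for TEAD, and to 1.82 for MYB. Distal ones turned to 0.419 for CDX, 0.884 for MEF2 and 0.778 for ONECUT, and to 1.49 for MYB and 1.33 for NFY. Against the same flanks distal CEBP rose to 1.81 and passed, and distal FOXA fell to 1.3 and still passed. With 50 bp windows, distal NFY was 1.19 and promoter NKX2 1.06, and in the stronger part by signal promoter NKX2 was 1.12. Leaving out a replicate gave 0.978 to 1.03 for distal NFY and 1.04 to 1.09 for promoter NKX2. Motifs below in distal regions numbered 3 in the stronger part, 2 with 50 bp windows and 2 to 3 without a replicate, instead of 5. At promoters 1 was below with the series IDR list, in the stronger part and with 50 bp windows. Between erythroid and hepatocyte regions, 3 motifs differed in the replicated list and 1 with 50 bp windows, instead of 0. Of 732 comparisons of genes named, 547 gave the same value or stayed within its spread.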

Other observations

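All tests in this part were chosen after the main values had been seen, and 18 gene families were picked by symbol.

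Gene families with a role in every cell had open promoters in fetal liver, and those of the senses and skin had almost none. Histone genes had a promoter region in 63 of 67 cases, cytosolic ribosomal proteins in 79 of 82, mitochondrial ribosomal proteins in 76 of 78, proteasome subunits in 36 of 40 and the minichromosome maintenance genes of DNA replication in 9 of 9 (exact test, adjusted p 0.00205). Olfactory receptor genes had 2 of 1134, vomeronasal receptors 1 of 330, keratins and keratin-associated proteins 2 of 113 and defensins 0 of 64. Genes of the Hox clusters, which pattern the body axis, had 0 of 39 promoters and no distal region in the conservative list (adjusted p 8.74e-12 and 0.0103), and 3 of 39 promoters in the pooled relaxed list. Zinc finger genes with a Zfp symbol had 285 of 394 (72.3% against 48.5% of other genes, adjusted p 7.48e-21).

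Families with some members that act in hepatocytes were mostly closed by the conservative threshold. Symbols do not separate those members from members of other tissues, so the shares describe whole families. Cytochrome P450 genes had 12 of 100 promoters open (adjusted p 1.10e-14), serpins 6 of 61, UDP-glucuronosyltransferases 0 of 22 and apolipoproteins 2 of 14 (adjusted p 0.0149). In the pooled relaxed list apolipoproteins had 10 of 14, no longer different from other genes (adjusted p 0.419), and cytochrome P450 genes had 24 of 100 (adjusted p 3.20e-11). The 6 GATA factor genes had 3 promoters open in the conservative list and all 6 in the relaxed list (adjusted p 0.0445). KLF factor genes had 14 of 17 (adjusted p 0.00777). Solute carriers had a promoter region in 48.8% of cases against 48.9% of other genes (adjusted p 1), and in 62.8% against 57.4% in the relaxed list (adjusted p 0.0437). They had 1.42 times the distal regions of matched genes (adjusted p 0.00288).

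Genes of chromosome X had open promoters less often than autosomal genes, with 312 of 948 (32.9%) against 50% (Fisher's exact test, odds ratio 0.490, p 2.09e-25). Without olfactory and vomeronasal receptor genes the shares were 33.2% and 53.8% (odds ratio 0.427). Depth per chromosome was unknown, and pools held both sexes.

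GATA sites, and the TAL1 composite that overlaps them, were commonest in the strongest distal regions. GATA sites lay at 41.2% of the strongest 3182 distal summits by signal and at 19.3% of the weakest 3182 (odds ratio 2.93, Fisher's exact test, adjusted p 2.61e-81). The TAL1 composite lay at 27.9% and 8.58% (odds ratio 4.13). CTCF sites went the other way, at 0.534% and 2.77% (odds ratio 0.189, adjusted p 2.22e-12), as did PU.1 of myeloid cells (1.10% and 2.07%, adjusted p 0.00613). FOXA and HNF4A were lower in the strongest than in the weakest (adjusted p 0.00828 and 0.00905) but did not fall steadily over 4 sets of equal size. From weakest to strongest, FOXA lay at 5.63%, 6.25%, 6.10% and 4.05% and HNF4A at 2.29%, 3.05%, 3.33% and 1.35%. NFE2 was higher in the strongest (2.42% and 1.45%, adjusted p 0.00905). KLF, RUNX and AP-1 did not differ past the threshold (adjusted p 0.0866, 0.0866 and 0.450).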
